A study of Mus musculus with 3 samples.

How the data were processed

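Bone marrow cells of C57BL/6 mice were sorted as DAPI-negative, lineage-negative and c-kit-positive and profiled as 3 droplet libraries of the 10x Genomics type, sequenced per the labels with 150 bp paired ends on an Illumina NovaSeq instrument. The control library came from a wild-type mouse, and the non_mCherry and mCherry libraries came from 1 mouse with Mx1-Cre and a heterozygous, poly(I:C)-inducible Runx1-Runx1t1 knock-in, split by the reporter. In this model Cre recombinase is switched on by the interferon response to poly(I:C), and cells without recombination lack the fusion and the reporter. The labels do not say whether the control mouse also received poly(I:C), so an effect of that treatment on mCherry or non_mCherry against control is not separable here. Groups came from the group label of each sample, with 1 library per group.

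The authors deposited, for each library, a sparse matrix of UMI counts with its cell barcodes and gene list. Each value was a whole count, and the smallest UMI total of a barcode was 500, 500 and 503 in control, non_mCherry and mCherry. Per the submitters' processing notes the counts were made with Cell Ranger 6.1.2 on mm10, while the file headers carry software version 3.1.0, and which of these made the counts is not settled here. Of 27998 gene identifiers, 27645 matched the GENCODE annotation of mm10, which gave the gene locations. Reads shared between Runx1t1 and the knock-in were assigned by the authors, and the knock-in sequence and mCherry are not in the gene list.

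The matrices held 9782 barcodes and 150702749 UMIs for control, 9751 and 92776556 for non_mCherry, and 11323 and 97404871 for mCherry, with median UMIs per barcode of 14728, 7634 and 7976. Barcodes with fewer than 1000 genes, fewer than 2000 UMIs or over 10% mitochondrial UMIs were left out, which kept 9066, 8056 and 10419 cells. Doublets were scored per library with Scrublet, as included in scanpy. Its automatic threshold called 0 cells in mCherry, so a common score threshold of 0.25 was set after the scores were seen, which left out 217 control (2.39%), 204 non_mCherry (2.53%) and 247 mCherry (2.37%) cells. Doublets of cells of the same kind cannot be found this way. The comparisons used 8849, 7852 and 10172 cells with 143311001, 86916116 and 92373057 UMIs. At this depth a gene at 20 CPM has over 1000 UMIs per library, so counting error is small beside the differences given, and genes near 0 CPM are given with their intervals or UMIs.

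For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes seen in at least 10 barcodes were scaled (values limited to 10), and 30 principal components, rounded so that a repeat gives the same digits, fed a graph of 15 neighbours. Leiden clustering at resolution 1.0 over the 3 libraries gave 25 clusters. Clusters were named from marker lists fixed before the data were examined (a mean marker score of at least 1.0, at least 3 markers 2-fold up, and no more markers of another class than of their own among the 10 genes furthest up), by a scoring rule set after the data were seen. The 4 unnamed clusters met the first parts of the rule and missed the last. By best score they were megakaryocyte (6.71% of control, 5.16% of non_mCherry and 0.02% of mCherry cells), monocyte and macrophage progenitor (1.09%, 0.739% and 0.029%), basophil and mast cell (0.011%, 0.166% and 16.6%) and stem and multipotent progenitor (0.011%, 0.344% and 24.9%). Running Leiden until the partition stopped changing was chosen after the data were seen, because results with its default number of passes changed with small numerical differences. The control library was also clustered alone, and each cell of the other libraries took the name of the majority of its 15 nearest control cells. This assignment was repeated from 10 starting points, also chosen after the data were seen. Numbers of mCherry cells nearest to control erythroid or megakaryocyte cells changed widely among them (7 to 2710 and 170 to 3719), so of these assignments the comparisons in the results use only the stem-nearest set (4062 to 6153 mCherry cells), and the others enter as alternative settings.

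For each pair of libraries, counts were summed over cells and divided by the library total to CPM, and the ratio was log2((CPM + 5)/(CPM + 5)). Fold values are plain quotients of CPM with exact intervals of the counts. Genes with at least 20 CPM in 1 of the 2 libraries entered the counts of genes with a ratio of at least 2. With 1 library per group, no test, standard error or p-value was computed. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, for counting error only, and a value of 0 has a floor of 3 counts. The design fixed in advance took as the main value for lists and genes the mean over cell strata with at least 100 cells in both libraries, or all cells together where fewer than 3 strata qualified. Non_mCherry over control had 9 strata. The mCherry comparisons had fewer than 3, and all cells together were used.

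There were 23 gene lists, fixed before the data were examined: fatty acid oxidation; fatty acid uptake, activation and storage; fatty acid synthesis and desaturation; cholesterol synthesis; glycolysis; tricarboxylic acid cycle; nuclear oxidative phosphorylation genes; mitochondrially encoded genes; cytosolic ribosomal proteins; interferon response; MHC class II; primary granule; secondary and tertiary granule; myeloid transcription factors and receptors; stem cell regulators; erythroid genes; genes described as raised and genes described as lowered by AML1-ETO; S phase; G2 and M phase; p53 response and cell death; immediate early and stress genes; and antioxidant and glutathione genes. Members with a mean of at least 5 CPM over the libraries were measured, and a member counted as higher or lower at a log2 ratio of at least 0.32 in size. The median was ranked among 10000 random lists of the same size drawn from 20 bins of expression. Some genes stand in several lists (Ly6a, Egr1, Gfi1, Cebpa, Cebpe, Mpo and Tal1, for example).

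The rule for named genes, also fixed in advance, took the 12 highest and 12 lowest genes by log2 ratio for each mCherry comparison and 6 of each for non_mCherry over control, among genes with at least 20 CPM in 1 of the 2 libraries in at least 50% of the strata and with the same direction in all strata with a sufficient level, where strata were used. Sex-linked, mitochondrially encoded, ribosomal, immunoglobulin and T cell receptor genes and unnamed gene models were passed over there. Up to 2 members furthest up and 2 furthest down of each list were added, and Runx1t1, Runx1, Kit and Mki67 were always named. For detection shares and phase calls (scanpy, with the S and the G2 and M phase lists), each cell was thinned at random to 3000 UMIs and shallower cells were left out.

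Alternatives fixed in advance were median-of-ratios scaling, totals without genes over 1% of a library, a pseudocount of 1 CPM, a lowest level of 5 CPM, all barcodes, doublets kept, thinned cells, resolutions of 0.6 and 1.5, clustering without cycle, interferon and sex-linked genes, names from nearest control cells, the mean over strata or all cells, and strata weighted by control. Added after the data were seen were the automatic doublet threshold, leaving out B lineage or basophil and mast cell clusters, stem-nearest cells alone, clustering without stress genes as well, clustering of thinned cells, and shares among cells other than B cell progenitor-like cells. The ratio and list steps were tested on simulated data, Poisson counts drawn around the mean profile of each pair of libraries at their depths: all genes given a true fold of 2.5 or 4.0 were found at 2-fold or more, 0 genes with a fold of 1.5 or 1.0 were, and 50 of 50 lists of 20 genes shifted by 0.5 (log2) ranked above percentile 97.5 in each comparison. Of 50 unshifted lists, 2, 1 and 1 lay outside percentiles 2.5 to 97.5. The simulated pairs shared 1 profile apart from 200 changed genes. Real libraries differ in many more genes, which widens the spread of random lists, so a shift of 0.5 can rank lower there. Free RNA was not removed, because the matrices hold called cells only, and no joint correction between libraries was applied, because each library is a group. Raw reads were not used here. Results for some single genes are not reported here.

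Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9.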

Results

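Stem and progenitor cells of the bone marrow, sorted as negative for DAPI and lineage markers and positive for c-kit, were compared in 3 single-cell libraries from 2 mice. The control library came from a wild-type mouse. The non_mCherry and mCherry libraries are sort fractions of the other mouse. It carried a poly(I:C)-inducible knock-in joining Runx1 to Runx1t1 (the AML1-ETO fusion of acute myeloid leukemia) with the reporter mCherry downstream. The labels do not say whether the control mouse received poly(I:C). The series asks how the fusion relates to fatty acid metabolism and to blocked differentiation before leukemia. Each group was 1 library, so no difference given here has a replicate check, and the 95% intervals cover counting error only.

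Both genes joined by the knock-in were higher in the library that the labels name mCherry. Runx1t1, the ETO part of the fusion, stood at 0.216 CPM in control (31 UMIs; 95% Poisson interval 0.147 to 0.307), 0.311 CPM in non_mCherry (27 UMIs; 0.205 to 0.452) and 8.49 CPM in mCherry (784 UMIs; 7.90 to 9.10), 39.2-fold and 27.3-fold higher in mCherry. Runx1, a transcription factor of blood development and the other part of the fusion, was at 148 CPM in control, 148 CPM in non_mCherry and 376 CPM in mCherry, 2.54-fold higher in mCherry than in either. These folds are over all cells of each library. In stem-nearest cells alone, Runx1t1 was at 1.09 CPM in control, 1.07 CPM in non_mCherry and 8.54 CPM in mCherry. Runx1 was at 166, 229 and 346 CPM there, so both differences were smaller than over all cells. In the mm10 annotation, Runx1t1 lies on chromosome 4 from 13743436 to 13893649 on the plus strand, and Runx1 on chromosome 16 from 92601466 to 92826149 on the minus strand. The mCherry sequence is not among the 27998 listed genes, and the sources do not say how much of the knock-in transcript is counted under mouse Runx1t1. Xist was at 916, 761 and 1768 CPM in control, non_mCherry and mCherry and Y-linked genes gave 1 UMI in all 3 libraries together.

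Nearly all reporter-positive cells grouped apart from wild-type cells. Of 10172 mCherry cells, 10122 (99.5%; 95% Clopper-Pearson interval 99.4 to 99.6) fell in 5 of 25 clusters that held 2 control cells (0.0226%) and 113 non_mCherry cells (1.44%; 1.19 to 1.73). Outside those clusters, mCherry cells gave no monocyte and macrophage progenitor-like, basophil and mast cell-like, megakaryocyte-like, eosinophil progenitor-like or plasma cell-like cell, so that each share was below 0.0295%, the share of 3 cells. Markers fixed in advance gave 3 of the 5 clusters the name stem and multipotent progenitor-like (58.1% of mCherry cells, and 49.2% to 65.3% over 10 clustering settings) and left the others unnamed, because a marker of another class stood among their leading genes and none of their own class did. Of these, 1 (16.6% of mCherry cells) scored highest as basophil and mast cell and 1 (24.9%) as stem and multipotent progenitor. In 7 of the 10 settings, 4.11% to 17.1% of mCherry cells were named basophil and mast cell-like, and in 6 of the 10 up to 6.26% were named megakaryocyte-like, so the absence of these classes outside the 5 clusters does not show that mCherry cells lack them. The 6.26% came from nearest control cells. Over 10 starting points of that assignment, 170 to 3719 mCherry cells were nearest to control megakaryocyte cells. Clusters without a name held 7.82% of control, 6.41% of non_mCherry and 41.5% of mCherry cells. A cluster drawn mostly from 1 library may be that library rather than a cell type, so the names of these 5 clusters were not used to compare shares.

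The mCherry-negative cells of the knock-in mouse spread over the same classes as control cells, with more B lineage cells and fewer myeloid progenitors. B cell progenitor-like cells made up 25.8% of the non_mCherry library (2024 cells; 24.8 to 26.8) and 0.497% of control (44 cells; 0.362 to 0.667). Granulocyte-monocyte and monocyte-macrophage progenitor-like cells together were 23.8% (22.9 to 24.8) against 43.6% (42.6 to 44.7) in control. These classes were combined after the data were seen, because their border moved with the clustering. Erythroid progenitor-like cells were at 20.4% (19.6 to 21.3) against 17.5% (16.7 to 18.3). Among cells other than B cell progenitor-like cells, a denominator chosen after the data were seen, the myeloid share was 32.1% against 43.9% and the erythroid share 27.5% against 17.6%. Basophil and mast cell-like cells were at 7.51% against 6.81% of all cells, neutrophil-like cells at 0.280% against 1.58%, T, NK and innate lymphoid cell-like cells at 2.59% against 1.57% (1.14% against 0.966% with thinned cells) and plasma cell-like cells at 0.548% against 0.124%. Shares of stem and multipotent progenitor-like, megakaryocyte-like, lymphoid-primed progenitor-like and eosinophil progenitor-like cells are not compared, because they moved with the clustering: over the 10 settings the control shares ran from 0% to 12.1%, 3.75% to 13.7%, 2.01% to 18.2% and 0% to 8.67%. The gate was the same apart from the reporter, while median depth was 15416 UMIs per control cell, 9247 per non_mCherry cell and 8179 per mCherry cell. The erythroid order turned when all barcodes were kept (19.6% of non_mCherry and 19.97% of control).

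**Figure D1:**
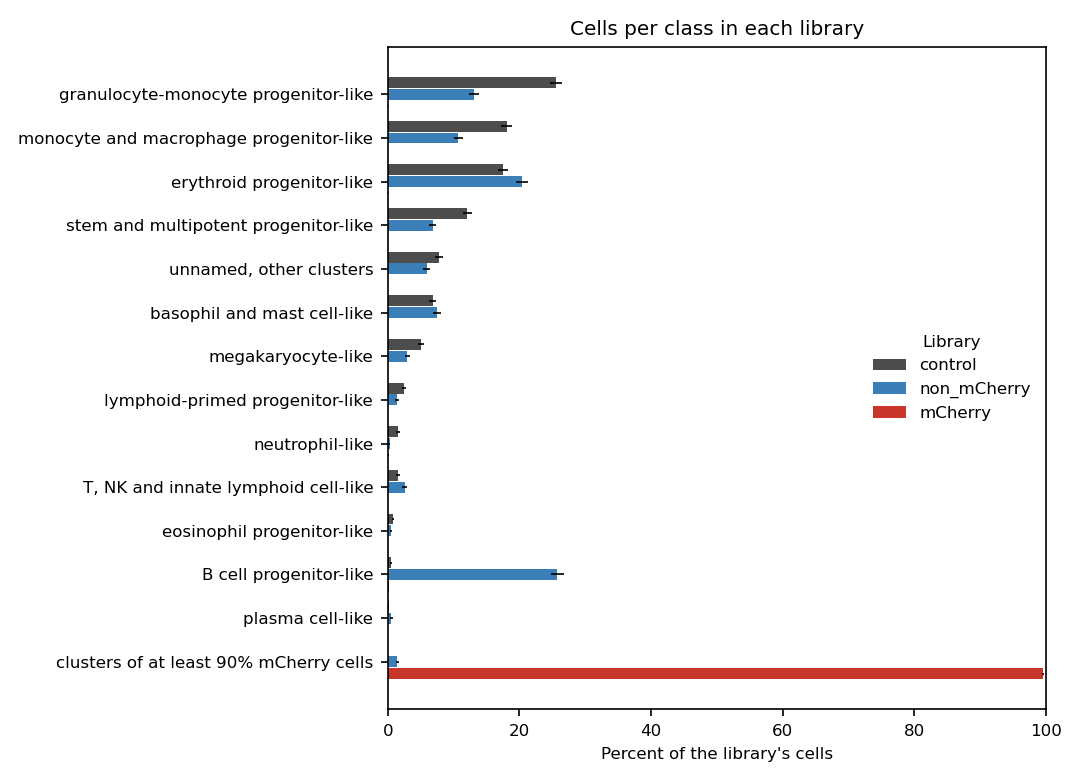
Percent of each library's cells (horizontal axis) per cell class (vertical axis) for control, non_mCherry and mCherry, with the 5 clusters of at least 90% mCherry cells as a class of their own; bars start at 0 and error bars are 95% Clopper-Pearson intervals. mCherry cells sit at 99.5% in their own clusters, and B cell progenitor-like cells at 25.8% of non_mCherry against 0.497% of control.

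The genes furthest up in mCherry over control included the mast cell genes Cpa3 and Cma1 and the stem cell antigen gene Ly6a, and those furthest down the neutrophil granule genes Elane and Prtn3. Cpa3, a carboxypeptidase of mast cells, was at 10477 CPM against 96.4 CPM, 109-fold higher (107 to 111), and Cma1, a mast cell chymase, 166-fold higher (152 to 182). Ly6a, which encodes the stem cell antigen Sca-1 and is induced by interferon, was 89.0-fold higher, at 658 against 7.40 CPM. At the other end, Elane, which encodes neutrophil elastase, was at 12.6 CPM against 2906, 231-fold lower, Prtn3, which encodes proteinase 3, at 63.5 against 4058 CPM, and Car1, a carbonic anhydrase of early erythroid cells, at 6.09 against 459 CPM. Among 6576 genes with at least 20 CPM in either library, 983 had a summed CPM ratio of at least 2 in favour of mCherry and 658 in favour of control. These counts describe size and are not counts of changed genes.

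Among the other genes furthest up in mCherry over control were the monocarboxylate transporter family member Slc16a11 (116-fold), the chemokine Ccl2 (73.1-fold), Clec4e (26.3-fold), Adamts9 (89.0 CPM against 7 UMIs in control), Csgalnact1 (35.0-fold), Lilr4b (66.9-fold), the amino acid transporter Slc7a8 (32.4-fold) and Cyp4b1 (80.7 CPM against 0.09 CPM). The other genes furthest down were Ly6c2, a monocyte surface antigen (1.83 against 462 CPM), the galectin Lgals1 (6.11 against 726 CPM), the basophil protease Prss34 (0.56 against 202 CPM), the eosinophil granule gene Prg2 (0.27 against 165 CPM), Slpi (0.58 against 162 CPM), Clec12a (1.13 against 170 CPM), F13a1 (0.48 against 121 CPM), Ms4a3 (18.2 against 481 CPM) and Hp (3.54 against 167 CPM). Mast cell Cpa3 and basophil Prss34 thus went opposite ways in mCherry cells. Kit, the receptor used for the sort, was at 269 against 66.8 CPM, 4.03-fold higher, and the proliferation marker Mki67 at 84.9 against 219 CPM.

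**Figure D2:**
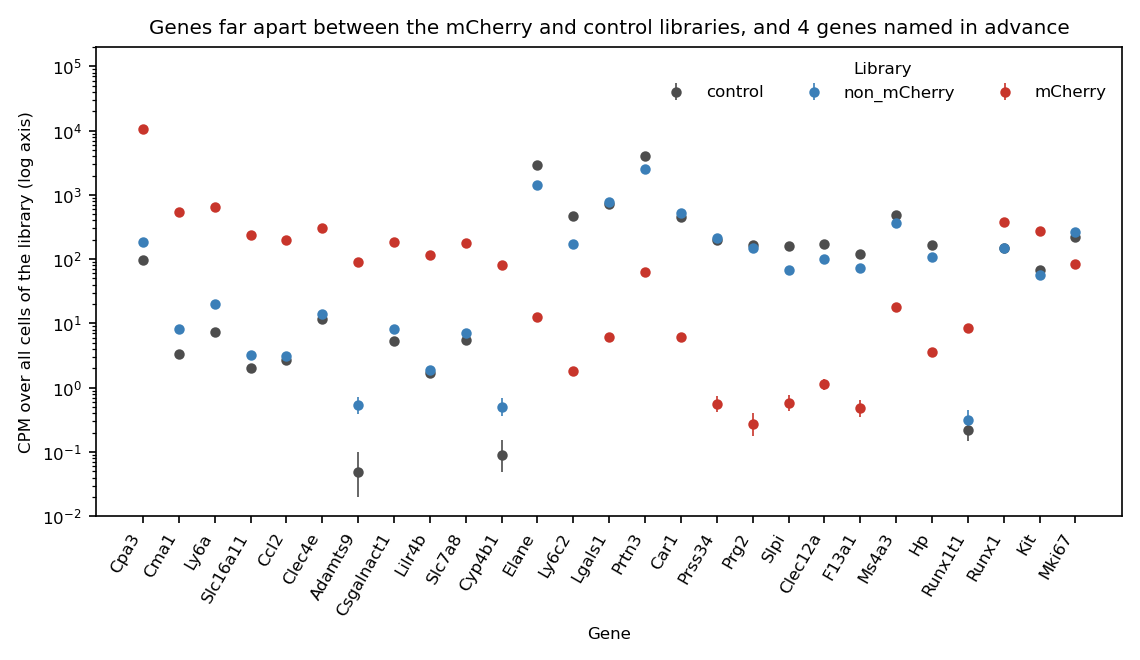
CPM over all cells of each library (vertical log axis) for genes named above as furthest up and furthest down in mCherry over control, and for Runx1t1, Runx1, Kit and Mki67 (horizontal axis), in control, non_mCherry and mCherry; error bars are 95% Poisson intervals of the counts. The non_mCherry values lie near the control values for most of these genes, with Cpa3 at 183 CPM in non_mCherry, 96.4 CPM in control and 10477 CPM in mCherry.

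Fatty acid genes showed no common direction between mCherry and control, whereas nuclear genes of oxidative phosphorylation and genes of cholesterol synthesis were lower. Of 23 measured genes of fatty acid oxidation, 5 were higher and 6 lower in mCherry by at least 0.32 (log2), the size used for all lists, with a median log2 ratio of 0.13 that turned to -0.06 with median-of-ratios scaling. Cpt1a, the entry step of fatty acids into mitochondria, was at 40.6 against 26.1 CPM, while Etfb (log2 ratio -0.90) and Acaa2 (-0.82) were lower. For uptake, activation and storage, 4 of 13 genes were higher and 5 lower (median 0.19), with the lipid droplet gene Plin3 at 1.43 (3.04-fold) and Acsl4 at 0.59, against the acyl-CoA synthetases Acsl3 at -1.14 and Acsl1 at -0.87. For synthesis and desaturation, 5 of 18 were higher and 7 lower (median -0.07), with the elongases Elovl7 at 2.17 (8.26-fold) and Elovl6 at 0.98, and Hacd1 at -1.29 and Hsd17b12 at -0.95. In cholesterol synthesis, 1 of 20 was higher (Srebf2, 0.85) and 13 lower (median -0.49), including Fdps (18.5 against 98.1 CPM) and Cyp51 (-1.18).

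Nuclear genes of oxidative phosphorylation were the most uniform of the energy lists in mCherry over control: 70 of 81 were lower and 2 higher, with a median log2 ratio of -0.71. The ATP synthase subunit gene Atp5g1 was at 269 against 911 CPM and the complex III gene Uqcrq at 133 against 427 CPM, while Cox7a2l (0.61) and Ndufa6 (0.55) were higher. The 13 genes encoded in mitochondria went the other way, with 8 higher, 1 lower and a median of 0.46: mt-Co1 was at 5251 against 2719 CPM and mt-Nd1 at 1279 against 1601 CPM. Other measures that bear on RNA quality moved with these lists: the median mitochondrial percent per barcode was 2.58 in mCherry, 1.96 in non_mCherry and 1.91 in control, and Malat1, a long noncoding RNA kept in the nucleus and chosen after its values were seen, was at 19760, 5315 and 4826 CPM. In the tricarboxylic acid cycle 16 of 22 genes were lower and 0 higher (median -0.49), including Idh3a (-1.38) and Sdhb (-0.90). In glycolysis 13 of 18 were lower and 4 higher (median -0.75): Ldhb was at 1.28 against 26.6 CPM and Pgam1 at 168 against 492 CPM, but the glucose transporters Slc2a3 (4.83-fold) and Slc2a1 (3.07-fold) were higher. Of 16 antioxidant and glutathione genes, 8 were lower and 0 higher (median -0.40), with Gsr at -1.93 and Gpx1 at -1.14. Cytosolic ribosomal protein genes were lower in 24 of 84 and higher in 5 (median -0.16), with Rps24 at 0.64 among the higher.

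Granule and erythroid lists were lower and stem cell regulators higher in mCherry than in control. Primary granule genes had 10 of 15 lower and 3 higher (median log2 ratio -2.21), and the exceptions included Serpinb1a (4.23-fold higher) and Cst7 (3.19-fold higher). Of 14 secondary and tertiary granule genes, 13 were lower and 1 higher (median -1.78), such as Pglyrp1 (-2.15) and Ngp (-2.15). Erythroid genes were lower in 16 of 21 and higher in 3 (median -1.69), with Ermap at 0.22 against 39.8 CPM, while the beta globin gene Hbb-bt (2.99-fold) and Tal1 (2.39-fold) were higher. Globin genes did not move together: Hbb-bs, also a beta globin gene, was at 42.3 against 289 CPM and Hba-a1 at 15.5 against 143 CPM. Stem cell regulators were higher in 16 of 22 and lower in 1 (median 1.35), led by Hlf (295 against 22.9 CPM) and Eng (194 against 27.7 CPM), with Hoxa9 lower at 18.0 against 32.6 CPM. Myeloid transcription factors and receptors split, with 12 of 24 higher and 8 lower (median 0.34): Egr1 (11.5-fold) and Id1 (7.12-fold) were higher, and Irf8, a factor of monocyte and dendritic cell fate, was at 15.5 against 263 CPM.

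Among genes described as lowered by AML1-ETO, 4 of 10 were lower in mCherry than in control and 5 higher (median log2 ratio 0.33). Cebpa and Cebpe, factors of granulocyte differentiation, were at 2.09 against 46.6 CPM and 3.31 against 48.8 CPM, but Gfi1 (6.62-fold) and Rassf2 (3.96-fold) were higher. Of 6 measured genes described as raised by AML1-ETO, 2 were higher and 1 lower (median 0.10), with Jup (13.8-fold) and Cdkn1a (1.45-fold) higher and Ccnd2 at -1.30. Interferon response genes were higher in 28 of 35 and lower in 2 (median 1.31), including Ddx58 (8.06-fold), with Gbp3 (-0.51) and Psmb8 (-0.44) lower. Whether the control mouse received poly(I:C), which raises an interferon response, is not given, so its effect is not separable here. MHC class II genes were higher in 3 of 7 and lower in 1 (median 0.24).

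Cell cycle genes were lower and immediate early genes higher in mCherry than in control. Of 42 S phase genes, 39 were lower and 0 higher (median log2 ratio -1.31), among them Rrm2 (11.9 against 111 CPM) and Gmnn (-1.97). Of 50 G2 and M phase genes, 41 were lower and 1 higher (median -0.80), among them Cks1b (-1.75) and Birc5 (-1.71). Immediate early and stress genes were higher in 14 of 16 and lower in 2 (median 2.62), with Zfp36 at 1364 against 120 CPM, whereas Ier3 (-1.94) and the heat shock gene Hsp90aa1 (-1.17) were lower. Such genes also respond to handling and sorting. In the p53 response and cell death list, 7 of 12 were higher and 4 lower (median 0.54): Trp53inp1 (9.34-fold) and the cell death gene Bcl2l11 (5.10-fold) were higher, and the survival gene Bcl2 was at 10.7 against 98.7 CPM, with Pmaip1 at 0.97 against 11.4 CPM.

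As a description of these libraries, list medians were ranked among 10000 random lists matched on expression. For mCherry over control, cholesterol synthesis, nuclear oxidative phosphorylation, both granule lists, erythroid genes, S phase and G2 and M phase lay at percentile 0, and interferon response, stem cell regulators and immediate early genes at percentile 100. Glycolysis lay at 0.13, the tricarboxylic acid cycle at 3.86, and mitochondrially encoded genes at 99.5. Fatty acid oxidation lay at 61.3, uptake, activation and storage at 60.1, and synthesis and desaturation at 18.6. Cytosolic ribosomal proteins lay at 98.0 although their median was negative, since most random lists of like expression had lower medians still. Antioxidant genes lay at 17.7, MHC class II at 63.7, myeloid factors at 95.6, the p53 list at 96.5, genes described as raised by AML1-ETO at 44.5 and those described as lowered at 83.7.

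Since nearly all mCherry cells lay outside the progenitor classes of control, the comparison was repeated, after the data were seen, in cells whose nearest control cells were stem and multipotent progenitor-like (6128 mCherry and 668 control cells). There 441 genes were at least 2-fold higher and 313 lower. The median was -0.42 for nuclear oxidative phosphorylation (51 of 81 lower), -0.59 for cholesterol synthesis, -1.14 for S phase, 0.64 for interferon response, 1.80 for immediate early genes and -0.02 for fatty acid oxidation. The erythroid median moved to -0.04, stem cell regulators to 0.32, primary granule genes to -0.85, secondary and tertiary granule genes to -0.56, glycolysis to -0.41, mitochondrially encoded genes to 0.10, G2 and M phase to -0.36 and the p53 list to 0.20. Cpt1a (-0.10) turned lower, Acsl1 (0.11) turned higher, and Cdkn1a was at -1.22. Cebpa stayed low at -2.60, while Cebpe was at -0.04. Hlf was at 355 against 221 CPM, Eng at 207 against 58.1 CPM and Hoxa9 at 22.7 against 85.5 CPM. Ly6a was at 672 against 69.4 CPM and Kit at 236 against 151 CPM, both smaller differences than over all cells. In these mCherry cells Cpa3 was at 8515 CPM, against 34.25 CPM in the control cells. Its log2 ratio of 7.76 was larger than the 6.69 over all cells, so sharing a nearest control class did not make the 2 sets alike. Cma1 was at 54.95 CPM in these mCherry cells, against 0 CPM in the control cells and 548 CPM over all mCherry cells. Over 10 starting points of the control clustering that defines these cells, the medians ran from -0.47 to -0.42 for oxidative phosphorylation, -1.30 to -0.84 for S phase, -1.22 to -0.10 for primary granule genes, 0.01 to 0.43 for stem cell regulators and -0.11 to 0.01 for erythroid genes, so the size of the stem cell regulator median in these cells, down to near 0, depends on the starting point.

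With median-of-ratios scaling instead of totals, the median over all genes moved by -0.18 (log2) for mCherry over control and by -0.17 for mCherry over non_mCherry. Of the genes at least 2-fold apart, the share in favour of mCherry then moved from 59.9% to 43.2% over control and from 61.2% to 45.0% over non_mCherry. Except for fatty acid oxidation, the list medians named here for these comparisons kept their direction under that scaling.

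Within the knock-in mouse, the reporter-positive fraction differed from the reporter-negative fraction much as it did from control, with B lineage genes added. Cpa3 was 57.2-fold higher in mCherry than in non_mCherry (56.3 to 58.1; 10477 against 183 CPM), Cma1 67.6-fold, Slc16a11 73.8-fold, Ly6a 33.0-fold, and the stem cell factor Hlf 27.1-fold (295 against 10.9 CPM). Elane was at 12.6 against 1435 CPM, 114-fold lower, and Lgals1 at 6.11 against 763 CPM. The surrogate light chain genes Vpreb1 (2.01 against 395 CPM), Vpreb3 (3.38 against 419 CPM) and Igll1 (0.45 against 246 CPM) and the B cell receptor gene Cd79a (2.72 against 240 CPM) were lower, as was Jchain (0.37 against 251 CPM). Among 6566 genes, 927 were at least 2-fold higher in mCherry and 587 lower, a description of size only.

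Further genes far up in mCherry over non_mCherry were Ccl2 (64.7-fold), the chromatin protein gene Hmga2 (29.5-fold), Rgs1 (20.2-fold), Lilr4b (60.5-fold), Adamts9 (168-fold) and Clec4e (22.1-fold). Further genes far down were Car1 (6.09 against 524 CPM), Prss34 (0.56 against 211 CPM), Prtn3 (63.5 against 2518 CPM), Prg2 (0.27 against 150 CPM) and Ly6c2 (1.83 against 174 CPM). Kit was 4.76-fold higher, and Mki67 was at 84.9 against 265 CPM.

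The median of each list had the same direction for mCherry over non_mCherry as over control, apart from MHC class II (median log2 ratio -0.10) and genes described as raised by AML1-ETO (-0.35, which was -0.02 without B lineage clusters). Nuclear oxidative phosphorylation genes were lower in 72 of 81 and higher in 3 (median -0.76), with Uqcrq at -1.67 and Atp5g1 at -1.62, and mitochondrially encoded genes were higher in 8 of 13 and lower in 0 (median 0.40), with mt-Co1 at 0.90. Cholesterol synthesis genes were lower in 14 of 20 and higher in 1 (median -0.54), with Fdps at -2.13 and Idi1 at -1.33. Fatty acid oxidation genes were higher in 6 of 23 and lower in 4 (median 0.12, or -0.03 with median-of-ratios scaling), with Cpt1a at 0.78 against Acaa2 at -0.71 and Etfb at -0.64. Uptake, activation and storage genes had a median of 0.23 (Plin3 1.24, Acsl3 -1.24), and synthesis and desaturation genes one of -0.18 (Elovl7 2.26, Hacd1 -0.98). Stem cell regulators were higher in 18 of 22 and lower in 1 (median 1.55). Interferon response genes were higher in 27 of 35 and lower in 4 (median 0.86), with Ddx58 at 2.11 and Ifi27l2a at -2.03. S phase genes were lower in 38 of 42 and higher in 0 (median -1.29), with Rrm2 at -2.91, and immediate early genes higher in 11 of 16 and lower in 2 (median 2.30), with Zfp36 at 3.71 and Fosb at 3.48.

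In stem-nearest cells alone (6128 mCherry and 285 non_mCherry), the counts for mCherry over non_mCherry were 327 higher and 184 lower. Cpa3 was at 733 CPM in these non_mCherry cells, against 34.25 CPM in stem-nearest control cells and 8515 CPM in mCherry. How many of them are among the 113 non_mCherry cells in the mCherry clusters was not counted. Any such cells would make the ratios given here smaller. The list medians were -0.29 for nuclear oxidative phosphorylation, -0.56 for cholesterol synthesis, 0.23 for interferon response, -0.50 for S phase, -0.12 for G2 and M phase, -1.28 for primary granule, -0.45 for secondary and tertiary granule, 0.49 for stem cell regulators, 0.16 for the p53 list and 1.59 for immediate early genes. The erythroid median, -1.34 in all cells, was 0.07 there. Hlf, 27.1-fold higher over all cells, was at 355 CPM in mCherry and 185 CPM in non_mCherry in these cells. Ly6a was at 672 and 183 CPM there, also a smaller difference than over all cells.

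**Figure D3:**
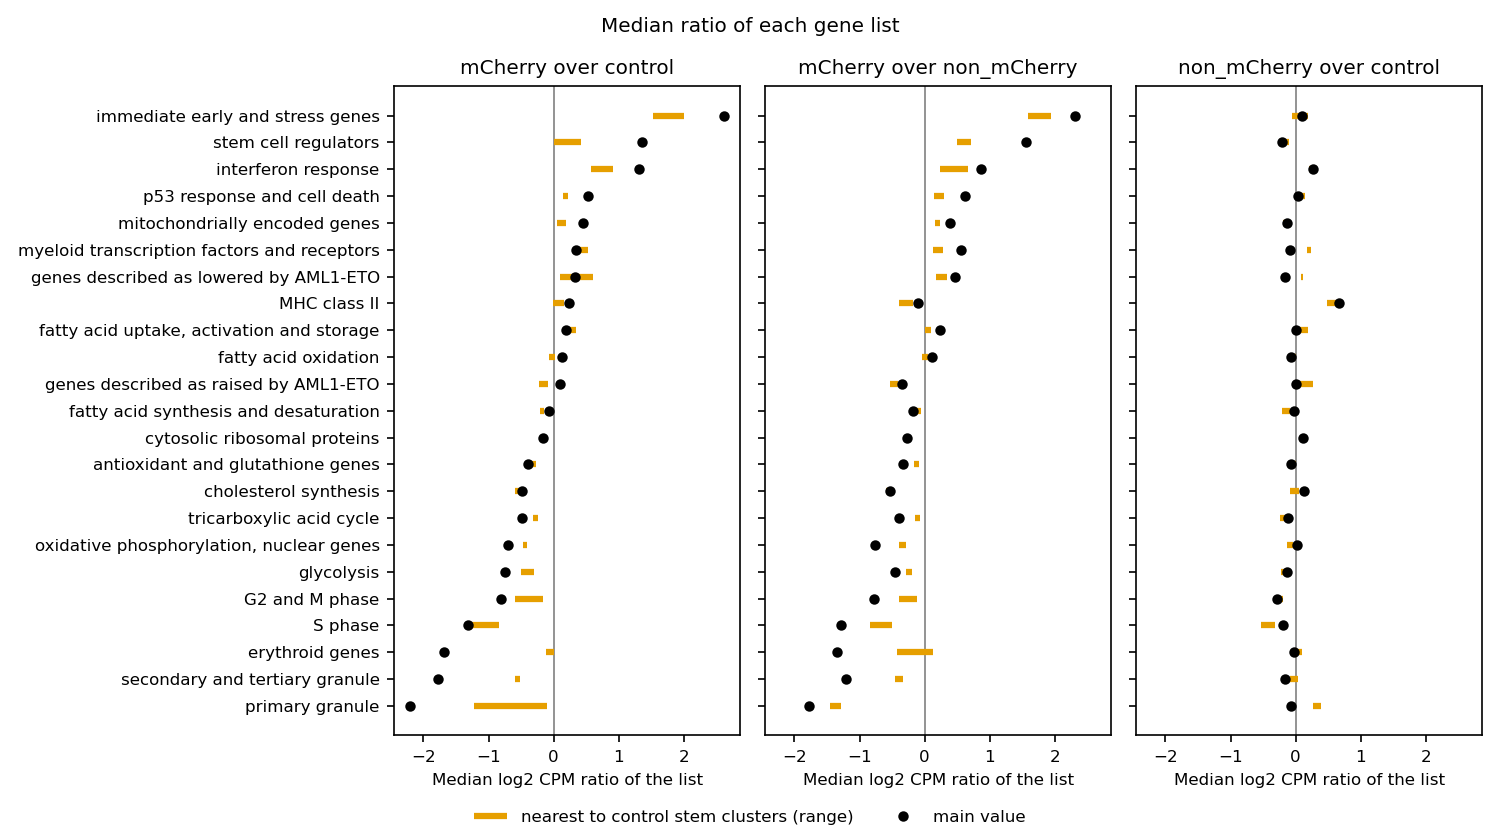
Median log2 CPM ratio (horizontal axis) of each of 23 gene lists (vertical axis) for the 3 comparisons; black points are the values over all cells (mCherry comparisons) or the mean over cell strata (non_mCherry over control), and orange bars span the values in cells nearest to control stem clusters over the starting points of the control clustering. Nuclear oxidative phosphorylation genes sit at -0.71 and -0.76 in the mCherry comparisons and at 0.02 for non_mCherry over control.

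The reporter-negative fraction lay close to control once cell classes were matched, with higher medians of the interferon and MHC class II lists. Averaged over 9 cell strata, interferon response genes were higher in 16 of 35 and lower in 0 in non_mCherry (median log2 ratio 0.27), including Ly6a (1.15) and the GTPase gene Igtp (0.76), while Isg15 (-0.01) and Ifit1 (0.00) stood level. An effect of poly(I:C), which the control mouse may not have received, is not separable from these values. MHC class II genes were higher in 4 of 7 and lower in 0 (median 0.66, and 0.33 over all cells), with Cd74 at 0.98. Over all cells H2-Aa stood at 0.13 (0.96 over strata), and H2-DMa and H2-DMb1 at -0.24 and -0.28 (0.03 and 0.02 over strata). The interferon regulator Irf1 (1.10) and the class I gene H2-Q6 (1.06) were among the genes furthest up, with Atf3 (1.01) and Wdfy1 (0.98). The B lineage genes Vpreb3 (2.38) and Vpreb1 (1.93) were furthest up although B cell progenitor-like cells were not among the strata. Free RNA was not removed, so its part in the strata, MHC class II transcripts included, is not separable here. The stem stratum held 608 non_mCherry cells, of which 535 lay outside the mCherry clusters. The rest lay in mCherry clusters with 0 control cells, so this stratum is not fully matched. Among genes furthest down were Cdk5rap1 (-1.22), Cd63 (-0.93), Ldhb (-0.89), Tceal8 (-0.80) and the immediate early gene Nr4a1 (33.5 against 74.7 CPM). Among 5631 genes, 62 were at least 2-fold higher in non_mCherry and 10 lower over all cells. Without B lineage clusters, a choice made after the data were seen, these were 17 and 8, and averaged over strata they were 15 and 2.

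Metabolic lists barely moved in non_mCherry over control. Medians were -0.08 for fatty acid oxidation, 0.00 for uptake, activation and storage, -0.03 for synthesis and desaturation, 0.13 for cholesterol synthesis, -0.13 for glycolysis, -0.11 for the tricarboxylic acid cycle, 0.02 for nuclear oxidative phosphorylation, -0.13 for mitochondrially encoded genes and 0.11 for ribosomal proteins. Cpt1a was at -0.39 and Acaa2 at 0.13. Stem cell regulators were lower in 6 of 22 and higher in 0 (median -0.21), with Hlf at -0.62. S phase genes were lower in 7 of 42 and G2 and M phase genes in 18 of 50, with 0 higher in both (medians -0.19 and -0.29), including Cdk1 (-0.61) and Cdca2 (-0.56). Over all cells the G2 and M phase median was 0.03, and Mki67 stood at 0.27 over all cells and at -0.38 over strata. Primary granule genes had a median of -0.07, with Elane at -0.69 and Mpo at -0.65, and -0.43 over all cells. The globin genes Hbb-bs (-1.48) and Hba-a1 (-0.98) were lower while the erythroid median was -0.02. Among transcription factors, Cebpa was at -0.46, and the monocyte antigen gene Ly6c2 at -0.84.

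Per-cell detection was compared after thinning each cell to 3000 UMIs, which left out 149 control, 635 non_mCherry and 123 mCherry cells that were shallower. Cpa3 was detected in 12.2% of control, 14.0% of non_mCherry and 99.3% of mCherry cells (20.4%, 20.9% and 99.9% unthinned), against 5.34% and 6.06% in erythroid progenitor-like cells of control and non_mCherry. Ly6a was detected in 2.44%, 5.35% and 70.3% (6.87%, 10.95% and 89.0% unthinned), against an erythroid background of 0.0651% and 1.26%. Hlf was detected in 7.23%, 3.55% and 51.6% (19.4%, 8.49% and 78.5% unthinned), against a background of 1.69% and 1.96%. Elane was detected in 48.3%, 29.1% and 0.149% (70.9%, 41.8% and 0.206% unthinned), against a background of 17.4% and 9.53%. The 41 mCherry cells outside the mCherry clusters gave Cpa3 in 48.8% (32.9 to 64.9), Ly6a in 12.2%, Hlf in 2.44% and Elane in 22.0%. They are not a clean background, since free RNA was not separated from their own transcripts. Among cells deep enough to be thinned, median depth before thinning was 12949 UMIs in control and 9373 in non_mCherry erythroid progenitor-like cells. Over all classes of such cells it was 15629, 9935 and 8216 UMIs in control, non_mCherry and mCherry. Runx1t1 was detected in 0.0920%, 0.194% and 2.60% (0.350%, 0.331% and 7.13% unthinned), against a background of 0.0651% and 0.0631%, so most mCherry cells gave no Runx1t1 UMI at this depth. Outside the mCherry clusters the non_mCherry share was 0.140% (10 of 7127 cells, against 14 of 7217 in all).

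Phase calls on thinned cells put 4.11% of mCherry cells in S phase (3.73 to 4.52), against 36.1% in control (35.1 to 37.1) and 30.6% in non_mCherry (29.5 to 31.7). G2 or M phase calls were 9.93%, 41.5% and 40.0%. Among stem-nearest cells, S phase calls were 3.86% in mCherry, 26.5% in control and 11.6% in non_mCherry, and G2 or M phase calls 6.24%, 11.3% and 11.2%. Such calls also read free RNA, which was not separated here.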

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

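The tests of depth, of cycle, interferon, sex-linked and stress genes and of a shift of the whole library for the clusters of mCherry cells, and those of Kit and of the cell filters for the B lineage cells, were chosen after the results they bear on were seen. All tests were run again after the clustering was set to run until it stopped changing.

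Among barcodes that the cell filters left out, those of non_mCherry (1695 barcodes) held Cd79a, a B cell receptor gene, at 1851 CPM, against 113 CPM in 716 control barcodes and 14.7 CPM in 904 mCherry barcodes. It was listed because barcodes outside the comparisons carry a signal above that of control.

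The first pattern is that 99.5% of mCherry cells lay in clusters of their own. Depth does not account for it, since the share was 99.5% (10002 of 10049 cells) when each cell was thinned to 3000 UMIs. The listed cell cycle, interferon, sex-linked and stress genes alone do not either: without them the share was 99.5% (10123 of 10172 cells). Genes outside the lists that respond in the same way stayed in the clustering, so such responses are not excluded. A shift of the whole library, from handling or free RNA, stays open, with values on both sides. It would raise the same genes in mCherry cells of another kind, and in 20 mCherry cells picked by UMIs of at least 4 of 11 B cell markers, whatever their cluster, 308 genes at least 2-fold higher than in non_mCherry and at 100 CPM or more had a median log2 ratio of 1.10 (0.40 to 1.56 over 1000 resamples of the cells) to 2231 non_mCherry cells picked in the same way, against 1.64 over all cells. Cpa3 was at 1994 CPM in the 20 cells and at 42.6 CPM in those non_mCherry cells. Of the 20 cells 3 lay in the mCherry clusters, and doublets of a B cell with another mCherry cell would raise the same genes. Against such a shift, the same 308 genes had a median log2 ratio of 1.48 in the 113 cells of the non_mCherry library in these clusters over other non_mCherry cells, and Cpa3 was at 498 CPM in the 50 mCherry cells of shared clusters against 10553 CPM in the mCherry clusters. Both sets of cells were picked by the clustering itself, so these values do not exclude it. A cell state tied to the fusion is left open beside it, on 1 mouse, with the sort for the reporter not separable from it.

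The second pattern is the 113 non_mCherry cells in the mCherry clusters, with Cpa3 at 9857 CPM, Runx1 at 331 CPM and a median of 4628 UMIs. Barcodes carried over from the mCherry library in sequencing are argued against, since 0.0% of these cells' barcodes were also mCherry cell barcodes (upper limit 3.21%), against 0.31% among other non_mCherry cells. Runx1t1 was at 9.26 CPM (5 UMIs; 3.01 to 21.6), a range that holds the mCherry value of 8.49 CPM and lies above the 0.255 CPM of other non_mCherry cells. That is consistent with cells of the mCherry gate in the wrong tube, and as much with cells that carry the fusion and fell below the reporter gate, a biological explanation that no value here separates from the first.

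The third pattern is the B cell progenitor-like share, 25.8% of non_mCherry against 0.497% of control. Depth and cell filters are argued against, since with all barcodes kept the non_mCherry share was still 46.7 times the control share. Entry of cells low in Kit through the sort gate is consistent with a Kit level in these cells of 0.388 times that of other non_mCherry cells (24.0 against 61.9 CPM). The few B cell progenitor-like control cells had a like ratio (21.4 against 66.9 CPM, from 7 UMIs), so low Kit marks the class in both libraries and does not say why its share differs. A difference between the mice in B cell development stays open as a hypothesis and was not tested.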

How the results depend on the processing

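The settings that leave out B lineage or basophil and mast cell clusters, keep stem-nearest cells alone, use the automatic doublet threshold, cluster thinned cells, leave stress genes out of the clustering or take shares among cells other than B cell progenitor-like cells were chosen after the data were seen. No paired analysis was possible because each group was 1 library, and no replicate spread exists to judge a move against. A value counted as moved when it left its counting interval (shares), changed by over 0.32 log2 (lists and genes) or by over 1.5 times (counts of genes). A list or gene at 0.32 or more in size counted as reversed when its sign changed, and smaller values that changed sign counted as stayed or moved. Depth limits genes near 0 CPM, such as Runx1t1, and detection per cell in the shallower libraries. The causes of moves were not tested, except where the setting's construction gives them.

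Of the alternatives fixed in advance, 35 of the counts of genes stayed within 1.5 times and 7 moved, 315 list medians stayed and 30 moved, and 61 shares stayed and 45 moved. For counts of genes and named genes, strata weighted by control were left out of these tallies. They gave 16 genes higher and 5 lower for non_mCherry over control, against 62 and 10 over all cells. For mCherry they gave 905 and 619 over control, against 983 and 658, and 839 and 465 over non_mCherry, against 927 and 587. No list median was reversed by that rule, while 12 changes of sign came from medians under 0.32 in size. Of those added later, 11 counts stayed and 7 moved, 115 list medians stayed, 22 moved and 1 reversed, with 10 changes of sign from smaller medians, and 42 shares stayed and 18 moved. Among named genes, 884 values stayed, 272 moved and 8 reversed under settings fixed in advance, and 408, 169 and 5 under those added later.

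In stem-nearest cells, which hold fewer cell classes by construction, genes at least 2-fold apart numbered 441 higher and 313 lower for mCherry over control, 327 and 184 for mCherry over non_mCherry, and 36 and 30 for non_mCherry over control. List medians for mCherry over control were -0.41 for glycolysis, 0.10 for mitochondrially encoded genes, 0.64 for interferon response, -0.85 for primary granule, -0.56 for secondary and tertiary granule, 0.32 for stem cell regulators, -0.044 for erythroid genes, -0.36 for G2 and M phase, 0.20 for the p53 list and 1.80 for immediate early genes. For mCherry over non_mCherry they were -0.29 for nuclear oxidative phosphorylation, 0.23 for interferon response, -1.28 for primary granule, -0.45 for secondary and tertiary granule, 0.49 for stem cell regulators, 0.067 for erythroid genes (reversed), -0.50 for S phase, -0.12 for G2 and M phase, 0.16 for the p53 list and 1.59 for immediate early genes. For non_mCherry over control they were 0.32 for primary granule and -0.54 for S phase. Genes that reversed there were Cpt1a (-0.10), Acsl1 (0.11) and Cdkn1a (-1.22) for mCherry over control, and S100a9 (0.42) for non_mCherry over control.

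Averaged over strata, the counts were 326 lower for mCherry over non_mCherry and 15 higher and 2 lower for non_mCherry over control. For the mCherry comparisons these strata came from nearest control cells and were unstable between starting points. The medians for mCherry over control were -0.28 for glycolysis, -0.48 for primary granule, -0.34 for secondary and tertiary granule, 0.67 for stem cell regulators, -1.22 for erythroid genes and 1.97 for immediate early genes, and Gbp3 reversed to 0.38. For mCherry over non_mCherry they were -0.40 for primary granule, -0.18 for secondary and tertiary granule, 0.85 for stem cell regulators and 1.73 for immediate early genes. With strata weighted by control, mCherry over control had -0.21 for glycolysis, 0.57 for MHC class II, -0.30 for primary granule, -0.22 for secondary and tertiary granule, 0.68 for myeloid factors, 0.84 for stem cell regulators, -1.15 for G2 and M phase and 2.20 for immediate early genes. The other mCherry comparison had -0.077 for glycolysis, -0.20 for primary granule, -0.10 for secondary and tertiary granule, 0.93 for stem cell regulators, -1.80 for erythroid genes, 0.91 for genes described as lowered by AML1-ETO and 1.91 for immediate early genes.

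For non_mCherry over control, the counts of genes higher and lower were 97 and 28 with thinned cells and 113 and 18 with at least 5 CPM, where more genes enter by construction, and 17 were higher without B lineage clusters. Over all cells together, the medians were 0.33 for MHC class II, -0.43 for primary granule, -0.54 for secondary and tertiary granule and 0.034 for G2 and M phase. Mki67, at -0.38 over strata, reversed to 0.45 with thinned cells, 0.27 with all barcodes, 0.28 with a pseudocount of 1 CPM, 0.27 over all cells together, 0.27 with median-of-ratios scaling, 0.27 with totals without genes over 1% and 0.31 without basophil and mast cell clusters. Single genes were summed over all cells in each of these settings, so by construction the sign goes with summing all cells and not with each setting. H2-Aa reversed to -0.26 with thinned cells. Without B lineage clusters, genes described as raised by AML1-ETO were at -0.018 for mCherry over non_mCherry. With a pseudocount of 1 CPM, erythroid genes were at -2.65 for mCherry over control.

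The share of mCherry cells in their own clusters was 92.2% with all barcodes, and 99.5% in the other clustering settings. The B cell progenitor-like share was 21.8% of non_mCherry with thinned cells, and 33.0% of non_mCherry and 0.705% of control with all barcodes. The combined granulocyte-monocyte and monocyte-macrophage progenitor-like shares of control and non_mCherry were 41.7% and 25.0% with thinned cells, 36.6% and 16.7% with all barcodes, 38.7% and 20.9% with doublets kept, 35.7% and 18.9% at resolution 0.6, 32.5% and 16.2% by nearest control cells, and 35.2% and 18.0% without cycle, interferon and sex-linked genes. The control share was 39.6% with the automatic doublet threshold, and the non_mCherry share 25.4% with stress genes left out as well. The erythroid shares of control and non_mCherry were 21.7% and 23.1% with doublets kept, 20.2% and 22.5% at resolution 0.6, 20.7% and 24.2% by nearest control cells, and 16.4% and 18.9% with the automatic threshold. With all barcodes the control share was 19.97%, and with thinned cells the non_mCherry share was 21.4%. Among cells other than B cell progenitor-like cells, the non_mCherry shares were 32.1% for the combined myeloid classes, 27.5% for erythroid, 10.1% for basophil and mast cell-like, 3.48% for T, NK and innate lymphoid cell-like and 0.738% for plasma cell-like cells.

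The basophil and mast cell-like shares of control and non_mCherry were 5.49% and 5.84% with all barcodes, 5.22% and 6.09% at resolution 0.6, 5.50% and 6.1004% by nearest control cells, and 7.58% and 8.28% with stress genes left out as well. The control share was 6.07% with doublets kept and 7.45% without cycle, interferon and sex-linked genes, and the non_mCherry share 8.21% at resolution 1.5 and 8.20% with the automatic threshold. Neutrophil-like cells were at 2.87% and 0.554% with all barcodes, and T, NK and innate lymphoid cell-like cells at 0.938% and 1.73% by nearest control cells and at 0.966% and 1.14% with thinned cells. The order of control and non_mCherry was the same in all 10 clustering settings for the B cell, combined myeloid, basophil and mast, neutrophil, T, NK and innate lymphoid, and plasma cell-like shares, and in 9 of them for erythroid cells. Control cells named stem and multipotent progenitor-like were 0% in 6 of the 10 settings, where non_mCherry cells were at 0.75% to 0.89%. The basophil and mast cell name moved in mCherry as well, with 0% of its cells so named in 3 settings and 4.11% to 17.1% in the others. For the megakaryocyte-like name the share of mCherry cells was 0% in 4 settings, 1.72% at resolution 1.5, 1.79% without cycle, interferon and sex-linked genes, 1.80% with stress genes left out as well and 6.26% by nearest control cells, which also named 26.6% of mCherry cells erythroid progenitor-like.

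S phase calls in control, non_mCherry and mCherry were 46.8%, 35.9% and 5.01% without thinning and 52.8%, 44.5% and 8.69% with all barcodes, and G2 or M phase calls 35.6%, 34.8% and 7.06%, and 32.7%, 33.8% and 9.16%. The mCherry share was lowest in each. By the share of cells with a UMI after thinning, Runx1t1 was 13.4 times as high in mCherry as in non_mCherry, and Runx1 1.75 and 1.76 times as high as in control and non_mCherry, a measure that saturates by construction for genes seen in many cells.

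Over 10 starting points of the control clustering, stem-nearest medians for mCherry over control kept their direction for nuclear oxidative phosphorylation (-0.47 to -0.42), cholesterol synthesis (-0.60 to -0.46), S phase (-1.30 to -0.84), interferon response (0.57 to 0.92), immediate early genes (1.52 to 2.01), stem cell regulators (0.01 to 0.43) and primary granule genes (-1.22 to -0.10). Fatty acid oxidation (-0.07 to 0.02) did not. For mCherry over non_mCherry, 9 starting points gave at least 100 cells in both libraries, and nuclear oxidative phosphorylation ran from -0.40 to -0.29 and erythroid genes from -0.43 to 0.13.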

Other observations

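Of the tests here, the one of cycling was chosen before its result was seen, and the use of stem-nearest cells was chosen after the data were seen.

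Mitochondrial genes of the nucleus and of the mitochondrial genome parted in the mCherry library. In stem-nearest cells of mCherry over control, nuclear oxidative phosphorylation genes had a median log2 ratio of -0.42, and mitochondrially encoded genes one of 0.10. A candidate explanation for the lower nuclear genes is that fewer mCherry cells were cycling. Among stem-nearest cells called G1 (5456 mCherry and 411 control cells) the median was -0.40, with 52 of 81 genes lower and 2 higher. Mitochondrially encoded genes stood about level there, with a median of 0.035 and 4 of 13 higher and 3 lower. S phase genes were still at -0.74 in the same cells, with 31 of 42 lower, and G2 and M phase genes at -0.27, so taking G1 calls did not remove the difference in cycling genes, the test decides nothing, and fewer cycling cells stay open. Against non_mCherry (207 cells) the median of the nuclear genes was -0.26 and that of S phase genes -0.27. In these cells fatty acid oxidation was at -0.05 and cholesterol synthesis at -0.59 for mCherry over control. No flux or protein was measured here.

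Among the barcodes left out by the cell filters, Malat1 was at 54490 CPM in mCherry, 22980 CPM in non_mCherry and 12040 CPM in control.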
